A study of Mus musculus with 7 samples.

How the data were processed

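RNA bound to GFP-tagged ribosomes was measured on 7 one-colour Affymetrix arrays. Per the labels, mice carrying a Cre-dependent ribosome tag were crossed to a line that expresses Cre from the activity-regulated gene Arc, and tamoxifen was given while the mice were exposed to cocaine or to shock. Cells active in that window keep a GFP tag on their ribosomes, and an anti-GFP antibody then pulled these ribosomes from medial prefrontal cortex (mPFC). Groups were taken from the labels: 4 cocaine-activated arrays (numbered 4, 5, 6 and 7) and 3 shock-activated arrays (numbered 4, 5 and 6). Precipitates of untreated mice and RNA from before the precipitation were not analysed here. Nothing in the labels says that the arrays came from separate animals or pools, so the p-values measure only the spread between these arrays, which may be technical in part.

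The deposited values were used as log2 expression values of 41345 probe sets, a scale read from the values, which ran from 1.12 to 13.44. The submitters' processing notes name Transcriptome Analysis Console. The summarization, background correction, normalization and probe set filters are not given in the sources used here. The quartiles were nearly equal on the 7 arrays (lower quartile 4.08 to 4.15, median 5.44 to 5.47, upper quartile 7.10 to 7.16), and 55.9% of the probe sets had an identical value on 2 or more arrays. A normalization that equalises the arrays removes any change in total RNA, so differences are relative to the other probe sets. Arrays have no read depth, and the number of arrays limits the precision.

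Probe sets were named through the platform annotation: 23521 had 1 gene symbol, 1814 had several, and 16010 were not listed there and are unnamed here. Of the probe sets with 1 symbol, 23328 had an Entrez identifier found in a RefSeq gene table of the GRCm38.p6 mouse assembly, and 0 of their symbols differed. No build is named for the array, so genome positions were not used here. For each gene the probe set with the highest mean over all 7 arrays was kept (1082 genes had more than 1), which left 22180 genes. No array detection call was used. As a stand-in for background, the 95th percentile of the mean levels of olfactory and vomeronasal receptor genes, which cortex is not known to use widely, was 5.44, and 13823 genes lay above it. Genes under it are called dim.

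Differences are cocaine minus shock on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 7 arrays, no covariate), with Benjamini-Hochberg adjustment over the 22180 genes at 0.05. A looser set took an unadjusted p under 0.05 with at least 1.5-fold. Gene lists were tested with limma's camera (two-sided, correlation between genes preset at 0.01, Benjamini-Hochberg over the lists), with an estimated correlation and with limma's fry as alternatives. Camera compares a list with the other genes, and fry asks if its genes move on balance one way. A list's score on an array is the mean over its genes of the value minus that gene's mean over the arrays. Npas4 was tested with an exact two-sided permutation test, and the separation of the groups over all genes with an exact one-sided one, both over the 35 splits of 7 arrays into 4 and 3. The smallest p these splits can give is 0.0286.

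Groups, tests, 25 gene lists, the rule for named genes and all alternatives but 1 were chosen before the data were examined. The lists cover immediate early and late activity-regulated genes, markers of neuron classes, cortical layers, striatum, glia, vessels and blood, and synaptic, receptor, peptide, stress, channel, ribosomal, mitochondrial, chemosensory and small RNA genes. Symbols had to match exactly, and 23 lists had a measured member. The rule named up to 12 genes per direction at adjusted p under 0.05, with the largest differences. Open places went to genes of smallest unadjusted p with at least 1.5-fold and groups that did not overlap, leaving out predicted genes, chemosensory receptors and small RNAs. From each list it took up to 4 members of smallest unadjusted p. Npas4, Fos, Arc, Slc17a7, Gad1, Gfap, Mbp and Rpl10a were always named. Members named outside the rule are marked as chosen after their values were seen.

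The alternatives were leaving out each array, quantile normalization, median centring, leaving out dim genes, the mean of a gene's probe sets, limma with trend and robust moderation, array weights, no moderation, the title number as a replicate block, and another distance. The exact permutation of each list's score was added after seeing the data. The scripts were tested on simulated data with the 22180 genes' means and spreads and independent genes. At an adjusted p under 0.05, 96% of 100 genes changed 2-fold and 67% of 100 genes changed 1.5-fold were recovered, and 15 unchanged genes were called. The changed genes were drawn at random, and the median within-group SD over genes was 0.093. These shares therefore do not hold for genes as variable between arrays as Npas4 (SD 0.32 in the cocaine and 1.21 in the shock group). A single shifted list was called by camera with either correlation and by fry. Genes of a list move together on real arrays, which that simulation leaves out.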

Results

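Ribosome-bound RNA of mPFC cells that had been active during cocaine (15 mg/kg on 2 days, 4 arrays) was set against that of mPFC cells active during shock (20 shocks of 0.5 mA lasting 2 s, on 2 days, 3 arrays). The comparison asks how the transcripts under translation differ between cells labelled by a rewarding and by an aversive experience. Among the 7 arrays, cocaine array 6 stood apart. Its correlations with the others were 0.983 over all genes, against 0.989 to 0.993 among the remaining 6, and its Euclidean distances to them averaged 37.2, against 23.9 to 29.6 between the remaining arrays.

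Immediate early genes, which neurons transcribe within minutes of strong activity, had higher values in the cocaine group. All 23 measured members had a higher mean in the cocaine arrays, with a median difference of 0.39 on the log2 scale. Npas4, an activity-dependent transcription factor (probe set 17361435, Entrez 225872), averaged 9.39 ± 0.32 (SD, n = 4) in the cocaine group and 7.91 ± 1.21 (SD, n = 3) in the shock group. Fos averaged 8.09 ± 0.52 against 6.91 ± 1.30, and the antiproliferative gene Btg2 averaged 8.26 ± 0.43 against 7.24 ± 0.74. Arc, whose promoter drove the labelling, averaged 9.51 ± 0.55 against 8.83 ± 0.91.

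None of these 4 genes separated the groups beyond the spread between arrays after correction. The Npas4 difference of 1.49 (SE 0.53) had an exact two-sided permutation p = 0.0571, where 0.0286 is the smallest possible. Shock array 5 had 9.11, above the 8.98 of cocaine array 6, while shock arrays 4 and 6 had 7.93 and 6.68. The difference was 0.87 without shock array 6 and 2.09 without shock array 5. Npas4 is a gene the study is known to have followed up and may have chosen on these arrays, so it is not independent evidence. By limma the unadjusted p was 0.0276 for Npas4, 0.0325 for Btg2 (difference 1.01), 0.0934 for Fos (1.18) and 0.199 for Arc (0.67). Fos differed by 0.64 without shock array 6 and 1.90 without shock array 5, and Arc by 0.36 and 1.20.

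**Figure D1:**
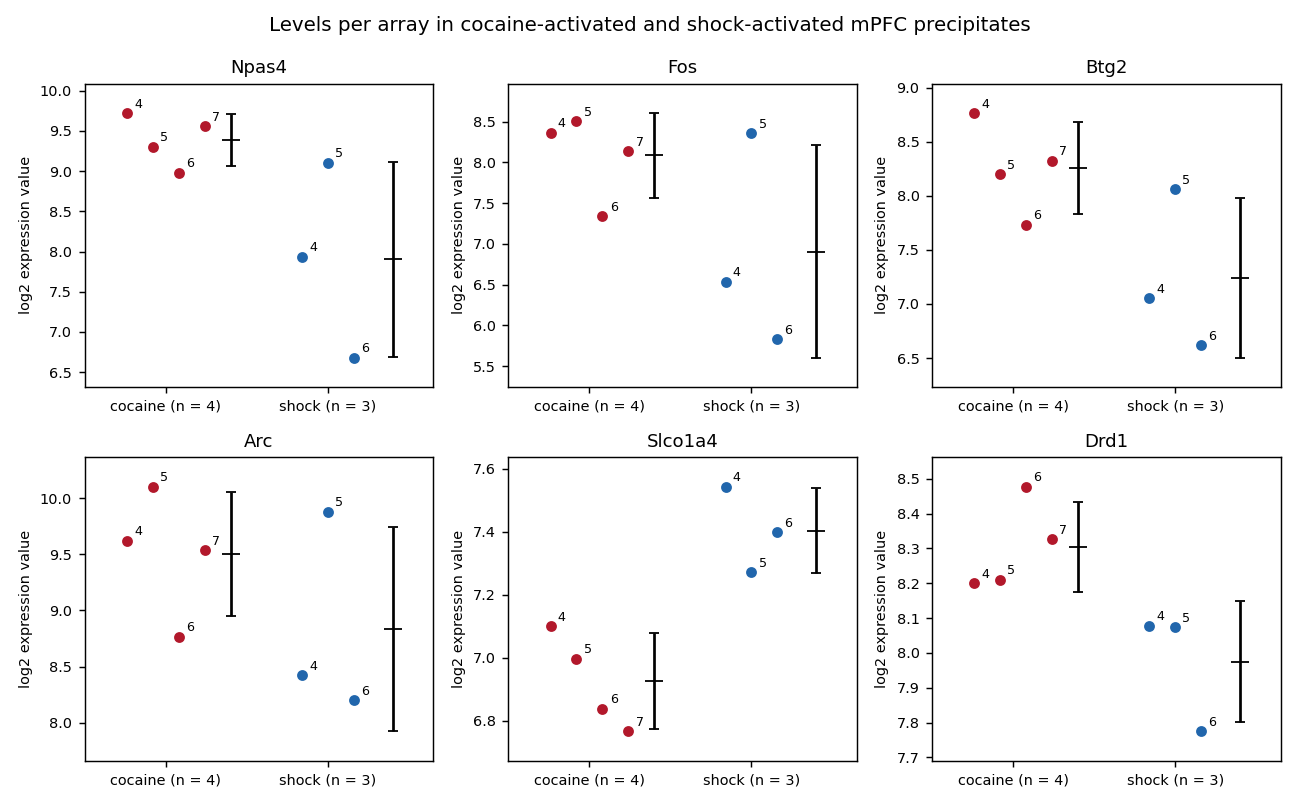
Log2 expression value (vertical axes) of Npas4, Fos, Btg2, Arc, Slco1a4 and Drd1 on each array, with array numbers beside the points and the mean ± SD of each group in black (n = 4 cocaine, n = 3 shock). Shock array 5 lies near the cocaine arrays for the 4 activity-regulated genes (Npas4 9.11), while the groups do not overlap for Slco1a4 and Drd1.

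As a group the immediate early genes were called higher by camera with the preset correlation (adjusted p = 3.95e-06). The call was lost with an estimated correlation (adjusted p = 0.834 with an estimated correlation), and an exact two-sided permutation of the list score gave p = 0.229. No member passed the adjustment over all genes, and 0 passed when adjusted over the list alone (smallest 0.373). The list score was 0.36 on shock array 5 and -0.22 on cocaine array 6, against -0.55 and -0.54 on shock arrays 4 and 6. Without shock array 4 the median was 0.18 and the preset call was lost (adjusted p = 0.0502), without shock array 5 it was 0.68, and without shock array 6 it was 0.23. Late activity-regulated genes, which follow hours after activity, were also called higher with the preset (16 of 20 higher, median 0.082, adjusted p = 0.00432, against adjusted p = 0.834 with an estimated correlation). Their named members were Rgs4 (difference 0.11), Pim1 (0.27), Nptx2 (0.20) and Rgs2 (0.080), and 0 passed when adjusted over the list alone. With the mean of the probe sets of a gene, Pim1 differed by 0.13 and Rgs2 by 0.051. With the kept probe set, the 0.080 of Rgs2 fell to 0.050 without shock array 4. This call was lost without cocaine array 5 (median 0.022), shock array 4 (0.0069) or shock array 6 (0.080), and the median was 0.14 without shock array 5.

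Vascular cell markers had lower values in the cocaine group. All 16 members had a lower mean there, with a median difference of -0.27. Slco1a4, a transporter of the blood-brain barrier, averaged 6.93 ± 0.15 (SD, n = 4) in the cocaine group and 7.40 ± 0.14 (SD, n = 3) in the shock group, and its groups did not overlap. Cldn5, a tight junction protein of brain endothelium, differed by -0.29, and the VEGF receptor genes Flt1 and Kdr by -0.30 and -0.19 (Kdr -0.094 without shock array 6). Camera with the preset correlation called the list lower (adjusted p = 4.04e-08), and the call was lost with an estimated correlation (p = 0.0751, adjusted p = 0.834 with an estimated correlation). Slco1a4 differed by -0.48 (SE 0.10) and was the 1 member past 0.05 when adjusted over the list alone (limma, adjusted p = 0.0344). Over all genes 0 members passed (limma, Slco1a4 adjusted p = 0.938). Without shock array 6, which had the highest vascular score (0.40), the median was -0.17 and the preset call held (adjusted p = 0.00102), as it did without each other array (medians of -0.33 to -0.20).

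Astrocyte markers were lower alongside them, in 13 of 13 members with a median of -0.13. Among them were the gap junction gene Gja1 (-0.23), the transcription factor gene Sox9 (-0.20), the membrane protein gene Mlc1 (-0.20), the water channel gene Aqp4 (-0.18) and Gfap (-0.16). Inhibitory neuron markers were lower in 16 of 20 members with a median of -0.087, including the somatostatin gene Sst (-0.19), the transcription factor genes Lhx6, Dlx2 and Sox6 (each -0.12) and Gad1 (-0.035), the gene of a GABA-synthesising enzyme. Camera with the preset called both lists lower (adjusted p = 8.48e-05 for astrocytes, 0.00151 for inhibitory neurons). Neither held with an estimated correlation (adjusted p = 0.834 with an estimated correlation in both). In both lists 0 members passed when adjusted over the list alone (smallest 0.328 and 0.445). The inhibitory call was lost without shock array 6 (median -0.053), and its median was -0.054 without cocaine array 4 and -0.14 without shock array 4. The astrocyte median was -0.20 without cocaine array 5. Without shock array 6, Gja1 differed by -0.13, Sst by -0.12, Lhx6 by -0.075 and Sox6 by -0.048, and without cocaine array 4 Dlx2 differed by -0.065. Shock arrays 4 and 6, with the lowest immediate early gene scores, had the highest vascular scores (0.15 and 0.40).

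**Figure D2:**
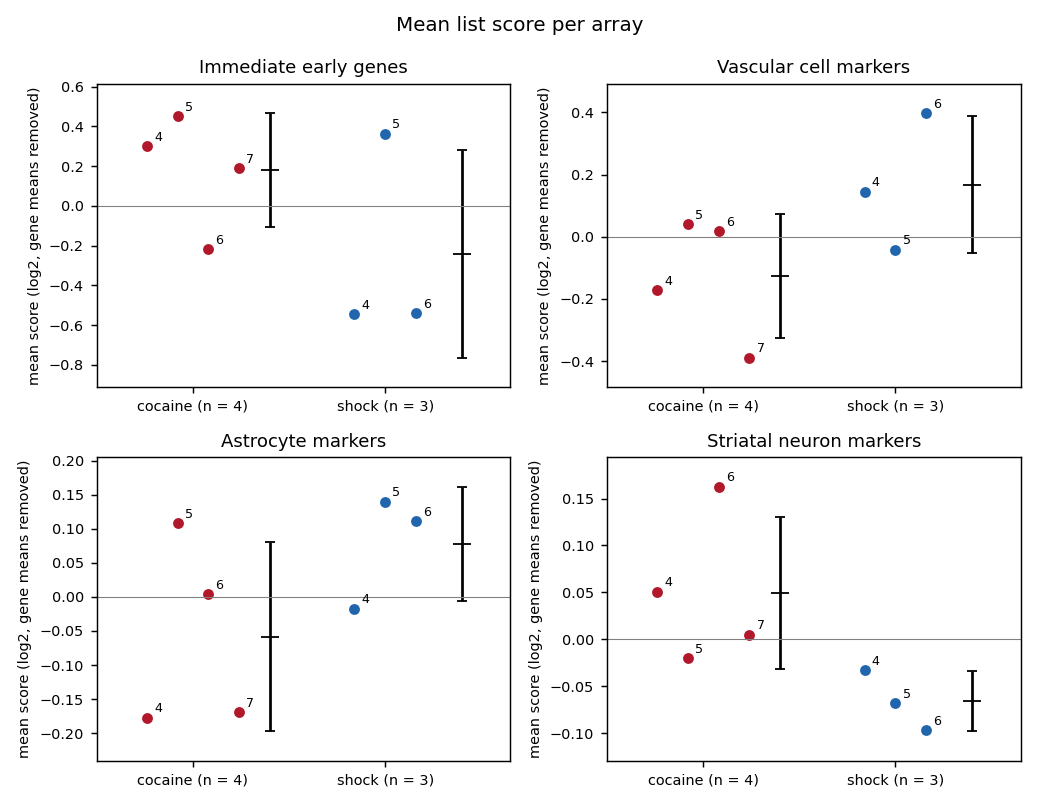
Mean score per array (log2, each gene's mean over the 7 arrays removed) of the immediate early genes and of the vascular, astrocyte and striatal markers, with array numbers beside the points and the mean ± SD of each group in black (n = 4 cocaine, n = 3 shock). The groups overlap for the first 3 of these lists, and for the striatal markers cocaine array 5 (-0.020) lies nearest to the shock arrays (-0.033 to -0.097).

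Striatal neuron markers had higher values in the cocaine group, in 10 of 12 members with a median of 0.11. The dopamine receptor gene Drd1 averaged 8.30 ± 0.13 (SD, n = 4) against 7.98 ± 0.17 (SD, n = 3), a difference of 0.33 (SE 0.10) with no overlap of the groups. The retinoic acid receptor gene Rarb differed by 0.23, the phosphodiesterase gene Pde10a by 0.17 and the tachykinin gene Tac1 by 0.14. Camera with the preset called the list higher (adjusted p = 5.78e-05), which was lost with an estimated correlation (p = 0.0699, adjusted p = 0.834 with an estimated correlation). Adjusted over the list alone, 0 members passed (smallest 0.0999). The highest striatal score was that of cocaine array 6 (0.16), the array that stood apart, and without it the median was 0.091. Chemosensory receptor genes, mostly under the background level, were called higher too (893 of 1373, median 0.055, adjusted p = 0.00151, against adjusted p = 0.834 with an estimated correlation). That call was lost without cocaine array 6 (median 0.016), which had the highest chemosensory score (0.17), and without shock array 4 (0.049). Quantile normalization (0.011) and array weights (0.034, adjusted p = 0.0591) lost it too. Leaving out dim genes kept only 69 of the list's members, since the dim level was set on this list, and their median was -0.011. Its named members were Olfr612 (0.20), Olfr320 (0.20), Olfr765 (0.19, dim) and Vmn1r204 (0.40, dim), and 0 of the list passed when adjusted over the list alone.

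The remaining 16 lists were not called by camera with the preset correlation, and the median of 14 of them changed sign when 1 array was left out, all but the excitatory and upper-layer lists. Of the 97 genes named by the rule, the differences of 50 turned or moved by over 1.5 times when 1 array was left out, as did those of 6 of the 9 with more than 1 probe set when the mean of the probe sets was taken. Excitatory neuron markers had a median of 0.012, which was 0.00385 without cocaine array 7 and 0.032 without shock array 5. Slc17a7, the vesicular glutamate transporter gene, averaged 11.73 ± 0.04 (SD, n = 4) against 11.65 ± 0.06 (SD, n = 3). Grin2a differed by 0.10, the dim gene Neurod1 by 0.12 and Baiap2 by 0.087. The upper-layer list had a median of -0.026 (Rorb -0.11, Pou3f2 0.11), which was -0.0051 without shock array 5. The deep-layer list had a median of 0.0054 and a mean of -0.00079 (Pcp4 0.10, Crym -0.091). Oligodendrocyte lineage markers had a median of 0.041 (Mbp 0.057, Mobp 0.15, Cldn11 0.14, Olig2 -0.16), which was -0.0084 without cocaine array 7 and 0.10 without cocaine array 6, and microglia markers one of -0.013 (Cx3cr1 -0.18, C1qb -0.13), which was 0.00067 after quantile normalization. Synaptic vesicle and postsynaptic density genes had medians of 0.013 and 0.020, with Cplx1 at 0.093, Shank3 at 0.12 (0.065 with the mean of its probe sets) and Shank1 at -0.081. For neuromodulator receptors the median was -0.0047 (0.0079 after quantile normalization) and the mean 0.015, with differences of 0.20 for the muscarinic receptor gene Chrm3, 0.21 for the serotonin receptor gene Htr1b and 0.16 for Drd2. Neuropeptide genes had a median of -0.017 (Npy -0.15, Pnoc -0.25), which was 0.052 without shock array 6 and -0.054 without shock array 4.

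Among stress and housekeeping genes, glucocorticoid-induced genes had a median of 0.035 (Dusp1 0.66, Fkbp5 0.079, Pdk4 -0.19), which was -0.018 without cocaine array 5 and 0.10 without shock array 5. Heat shock and unfolded protein response genes had one of 0.024 (Hspb1 -0.30, or -0.19 with the mean of its probe sets, and Hspa1a 0.17), which was -0.018 without shock array 4. Axon guidance genes had a median of -0.0055, which was 0.0057 after median centring, and voltage-gated channel genes one of 0.013 (Kcna1 0.10, Kcnd2 0.093, Kcnh5 0.11 and the dim gene Kcnv2 -0.26). Cytosolic ribosomal protein genes had a median of -0.00058 and a mean of 0.017, with Rpl37 at 0.26 and Rpl17 at 0.33, and the median was 0.0020 after quantile normalization. Rpl10a, whose tagged product marks the ribosomes in this kind of mouse, averaged 11.89 ± 0.10 (SD, n = 4) against 11.86 ± 0.07 (SD, n = 3). Oxidative phosphorylation genes had a median of 0.019 with 52 of 76 higher (Cox5b 0.23, Uqcrh 0.10), at adjusted p = 0.124 by camera with the preset and adjusted p = 0.897 with an estimated correlation. The preset called that list higher with dim genes left out (adjusted p = 0.0249), without cocaine array 7 (0.0128) and without shock array 6 (0.0077). Camera with an estimated correlation lost each of these calls (adjusted p = 0.804, 0.909 and 0.9375). The median of that list was -0.00074 without shock array 5. Small noncoding RNA genes had a median of 0.0097, which was -0.0072 after quantile normalization, with Snord118 at 0.43 and the dim genes Mir290a and Mir216a at 0.48 and -0.31. No gene of these 16 lists passed when adjusted over its list alone. The lists of red blood cell genes and of mitochondrial genome genes had 0 members among the named genes.

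**Figure D3:**
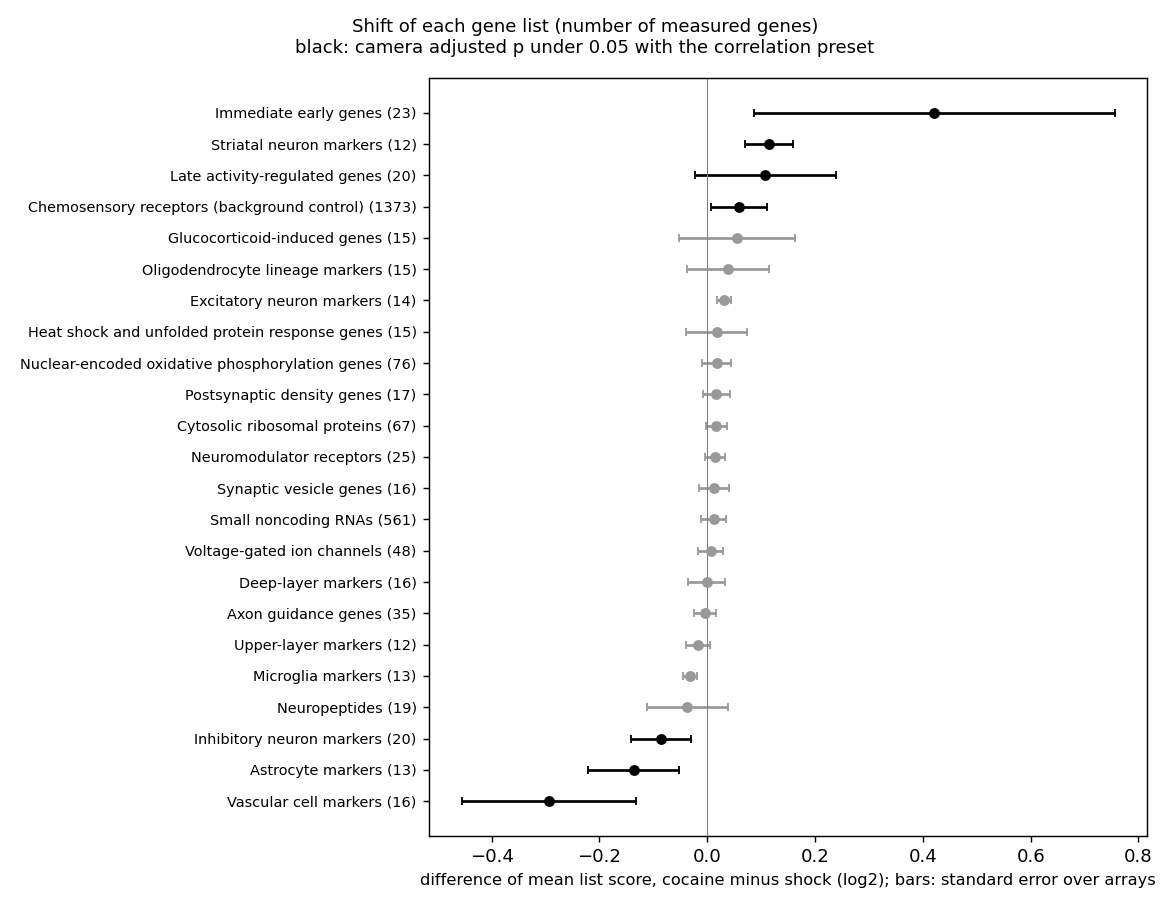
Difference of the mean list score, cocaine minus shock (log2, horizontal axis), for the 23 measured gene lists, with the number of measured genes in brackets and bars of 1 standard error over the arrays. The 7 lists in black passed camera with the preset correlation of 0.01, and 0 of the 23 passed with an estimated correlation; the immediate early genes have the widest bar (difference 0.42, SE 0.33).

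Across all 22180 genes, 0 passed limma's adjusted p threshold (smallest adjusted p = 0.938), and 0 passed under each alternative run. At an unadjusted p under 0.05 there were 688 genes, 339 higher and 349 lower in the cocaine group, where 1109 are expected with no difference. The groups did not overlap for 525 genes (2.37%). Chance would give 5.71% for values without ties. A tie between the groups counts as overlap here, and 55.9% of the probe sets had an identical value on 2 or more arrays. The 2 shares can therefore not be compared. The looser set at 1.5-fold held 11 genes, of which 7 were dim and 4 chemosensory receptors, and 34 genes without shock array 5. Its higher genes included Npas4, Btg2 and the stress-responsive gene Gadd45g (difference 0.68), the last chosen after its values were seen. Apart from Npas4 and Btg2, which it named through their list, the rule for named genes took 3 of the 11 for its places per direction. These were Gsdmc, a gasdermin gene (0.60, dim), the pseudogene Gpx2-ps1 (-0.70, dim) and Speer4c (-0.62, one of a family of similar copies, so uncertain). None of the 3 passed the correction (limma, adjusted p = 0.938). Distances between groups averaged 29.0 and those within groups 29.7, a difference of -0.695 (exact one-sided permutation p = 0.6). Cocaine array 6 lay far from every array, which lowers this difference in splits that place it in the group of 4, as the real one does. The test could therefore hardly reach a small p. Without cocaine array 6 the difference was 0.035 (exact one-sided permutation p = 0.4). It was also positive without cocaine array 4 or 5, up to 0.50 (without array 5, exact one-sided permutation p = 0.3). Of the 23 lists, 7 passed camera with the preset correlation (4 without shock array 4) and 0 passed with an estimated correlation, by fry (smallest adjusted p = 0.897) or by the exact permutation of scores (smallest adjusted p = 0.657). By that permutation 0 lists had an unadjusted p under 0.05.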

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

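The tests of a compressed signal range and of a swap were chosen after the distances between arrays had been seen (the bright genes were added to the former after their values were known), and the striatal test used genes listed after the results of the first lists were known.

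Among the 4 cocaine arrays, the mean distance of array 6 to the other arrays stood apart, with a gap to the nearest array of 0.9746 of the range. The same gap was 0.9089 for the upper-layer score of cocaine array 5, which was the highest. Cocaine array 4 was lowest for Calb1 (0.9271), Dlx2 (0.9104), Sox6 (0.8519) and Bsn (0.8337). Cocaine array 7 was highest for Grin2a (0.9319), Cplx1 (0.8969) and Dlgap2 (0.86). Cocaine array 6 was lowest for Cx3cr1 (0.9105) and Lhx6 (0.8987) and highest for Epha7 (0.8821). Cocaine array 5 was lowest for Kcnv2 (0.9028) and highest for Hspa1a (0.8359). These 14 of 123 measures passed Dixon's 95% limit for 4 samples, where chance passes about 5% of independent measures without ties, here 6.15. Identical values on 2 or more arrays were frequent, in 55.9% of the probe sets. Calb1, Bsn, Sox6, Kcnv2, Hspa1a and Dlgap2 each had the same value on 2 cocaine arrays, which favours a large gap. Whether 14 exceeds chance can therefore not be read from 6.15. The shock group, with 3 arrays, was not tested this way.

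On cocaine array 6, 1012 genes lay more than 0.5 on the log2 scale from the mean of the other arrays, against 168 to 268 on each other array. A swap with a shock array cannot be told apart by distance: its mean distance to the shock arrays was longer by 0.674 than that to the other cocaine arrays (37.5 against 36.8), but the other 6 arrays did not separate by distance either (difference of 0.035 between and within groups without it, exact one-sided permutation p = 0.4). A compressed signal range was not settled either: its deviation fell with the mean level with a slope of -0.0262, outside the -0.0036 to 0.0088 of the other arrays, and its genes under 5 on the log2 scale lay 0.039 higher in the median, but its genes over 10 were not lowered (0.0012, within the -0.0071 to 0.0108 of the other arrays). More striatal tissue in the dissection may also contribute, as the held-out striatal markers scored 0.0640 above the next array, though several of them, such as Pde1b, Foxp1 and Meis2, are also used by cortical neurons. No biological explanation was tested, because the design names none for a single array.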

How the results depend on the processing

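The exact permutation of list scores was chosen after seeing the data. The count of 0 genes at adjusted p under 0.05 held under every alternative run (limma, or the plain linear model without moderation; smallest adjusted p from 0.531 with dim genes left out to 0.980 without shock array 4). The 11 genes at unadjusted p under 0.05 and 1.5-fold became 20 with the replicate block, 4 with dim genes left out (fewer genes tested), 5 without moderation, and 8 to 34 leaving out 1 array, the cause of which was not tested. The share higher in the cocaine group was 72.7% of the 11, 66.7% of 9 after quantile normalization, 62.5% of 8 with array weights, 60% of 5 without moderation, 50% of 14 without shock array 4 and 85.7% of 14 without cocaine array 4. The 7 lists became 0 with an estimated correlation, 0 by fry and 0 by exact permutation, each of which takes the correlation between genes from the data, and 4 to 8 leaving out 1 array. The chemosensory list turned to -0.011 with dim genes left out. The overall separation of the groups ran from -2.23 to 0.50 leaving out 1 array and turned positive without cocaine array 4, 5 or 6. Leaving out 1 array also turned Gad1 (-0.090 to 0.048), Rpl10a (-0.0026 to 0.078), Baiap2 (-0.0019 to 0.14), Syp (-0.00028 to 0.072) and Cspg4 (-0.14 to 0.0033), for which the cause was not tested. The Npas4 difference ran from 0.87 to 2.09. The title numbers were not taken as pairs, since the labels do not say what they mark. The correlations of deviations were all positive for the same number (0.128, 0.0639 and 0.158 for numbers 4, 5 and 6). Those for different numbers ran from -0.118 to 0.0900, and shock array 5 correlated best with cocaine array 7 (0.0900). A factor shared by number is therefore not excluded, and the unpaired tests would ignore it. With the number as a block, 915 genes had an unadjusted p under 0.05 by limma, against 688 without it. With the replicate block, which leaves cocaine array 7 without a partner, Npas4 differed by 1.43 (limma) and 8 lists passed, oxidative phosphorylation added (adjusted p = 0.0115), as already without that array (1.43, 8 lists, adjusted p = 0.0128). With an estimated correlation 0 passed in the block (smallest adjusted p = 0.607). Genes under the background level of 5.44 are limited by signal over background.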

Other observations

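All tests here but the counts of splits for the looser gene set and for the number of lists were chosen after the results they bear on, or the array values behind them, had been seen. The prediction for the held-out vascular genes was written before their own values were seen, but after those of the first vascular list.

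Genes of other cells around vessels were looked at with lists written after the first lists' results were known, with 0 genes shared with those lists. All 18 endothelial genes outside the first vascular list had a lower mean in the cocaine group, with a median of -0.18 (exact two-sided permutation p = 0.0571 for the score). They included the drug efflux pump gene Abcb1a (-0.26), the cadherin gene Cdh5 (-0.30) and the thyroid hormone transporter gene Slco1c1 (-0.29). Mural cell genes were lower in 13 of 14 (median -0.21, p = 0.171 by the same permutation), and fibroblast and meningeal genes in 11 of 12 (median -0.22, permutation p = 0.171), with Bgn at -0.46 and Dcn at -0.42. Genes of choroid plexus and ependyma were lower in 6 of 8 (median -0.13, permutation p = 0.257). Further astrocyte genes were lower in 15 of 16 (median -0.14, permutation p = 0.257), with Slc39a12 at -0.32, and further striatal genes higher in 12 of 14 (median 0.095, permutation p = 0.114), with Scn4b at 0.29. Without shock array 6 the score difference went from -0.21 to -0.12 for mural genes and from -0.20 to -0.12 for fibroblast and meningeal genes (-0.30 without shock array 5). That of choroid plexus and ependyma, -0.24, was -0.13 without shock array 4, -0.15 without cocaine array 6 and -0.38 without shock array 5, and that of further astrocyte genes, -0.15, was -0.096 without cocaine array 4 and -0.10 without shock array 5. None of the 6 passed 0.05 by this permutation, or by camera with an estimated correlation after adjustment (smallest for the endothelial list, unadjusted p = 0.0329, adjusted p = 0.197 over the 6, the others at an unadjusted 0.0999 to 0.219). These genes were picked to illustrate the lists after their values were seen.

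The real count of 0 genes at adjusted p under 0.05 (limma, highest other split 0) cannot be tested against other splits of the 7 arrays, since each gives at least 0. For the looser set, 22 of the 35 splits gave as many as the real 11 (highest other 33), and for the lists past camera with the preset correlation, 13 of 35 gave as many as the real 7 (highest other 14). Chance could be excluded for neither the looser set nor the lists. The split with 33 genes set cocaine arrays 6 and 7 and shock arrays 4 and 6 against the rest, and that with 31 set cocaine arrays 4, 5 and 7 and shock array 5 against the rest. Whether such highest counts exceed chance was not tested.

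The higher immediate early genes in the cocaine arrays were weighed against chance, scaling and cell content. For scaling, 450 genes matched on mean level had a median difference of 0.0052, against 0.39 for the list. No offset of the list's size therefore remains at these levels. Arrays that are already equalised hold such a median near 0, so the matched genes cannot decide whether scaling played a part. They replaced quantile normalization, which also left 0.39 but moves little in such a table. A smaller share of excitatory neuron RNA in the shock arrays, by a like amount, is argued against by the excitatory markers. Their score differed by 0.031 (SE 0.014), or 0.019 without cocaine array 7. These markers cover labelled and unlabelled neurons alike, so the share of RNA from labelled cells was not tested. Chance could not be excluded, since 8 of 35 splits gave a score difference as large (real 0.42, highest other 0.76; 0.27 without shock array 4 or 6, 0.72 without shock array 5), and a difference between cocaine and shock stays open beside it, as do untested differences in handling or in the time from the last exposure.

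For the lower vascular markers in the cocaine arrays, a like drop in RNA of every non-neuronal cell type is argued against. Oligodendrocyte and microglia markers together differed by 0.0059 (SE 0.036), or -0.016 without cocaine array 7 and 0.025 without cocaine array 4. This value pools lists that went opposite ways: oligodendrocyte markers differed by 0.038 (SE 0.076) and microglia markers by -0.031 (SE 0.013). A small drop in microglia RNA is therefore not excluded. Astrocyte markers were left out of this value and were lower (score difference -0.14, SE 0.085). A drop shared by vascular cells and astrocytes is thus not argued against. The held-out endothelial and mural genes, whose score differed by -0.198 (SE 0.094), go with a lower content of vascular RNA. They mark the same cells on the same arrays as the first list, so they are not independent evidence. Among the most abundant of these, Slc2a1 averaged 9.24 against 9.37 and Slc7a5 9.17 against 9.35. Fibroblast and meningeal genes were lower too, in 11 of 12. Whether the content differed in the dissected tissue or through the anti-GFP precipitation was not tested, since RNA from before the precipitation was not analysed here. Chance could not be excluded, with 6 of 35 splits as large in either direction (real -0.29, or -0.18 without shock array 6, highest other 0.35). Lower expression within vascular cells after cocaine was not separated from lower content.

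Npas4 differed more than the other immediate early genes, a comparison taken up after their array values had been seen. Npas4 minus the mean of the other 22 differed by 1.11 (SE 0.51), with an exact two-sided permutation p = 0.0286, the smallest these splits can give, and every cocaine array (0.76 to 1.36) lay above every shock array (-0.95 to 0.64). Without shock array 6 the difference was 0.63 (SE 0.19, exact two-sided permutation p = 0.0667, the smallest that 4 against 2 arrays can give). The same comparison over all 23 genes of the list gave Npas4 an adjusted p of 0.493 (Benjamini-Hochberg, exact permutation), so it fails the correction. Npas4 also had the widest range over the arrays in this list (3.04, with Fos next at 2.68). A gene of wide range differs from the mean of the others even where it only follows the shared activity level of an array. The comparison cannot tell that from a response beyond this level. With 1 gene picked from 23 on the same 7 arrays, such a response stays a hypothesis.

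Late activity-regulated genes followed the immediate early genes from array to array. Pearson's r of the list scores over the 7 arrays was 0.897 (permutation p = 0.00377, adjusted p = 0.0189 over 5 relations by Benjamini-Hochberg, exact permutation) and Spearman's rho was 0.964 (exact permutation p = 0.00278). Without shock arrays 4 and 6, the farthest from the median, r was 0.814, and with group means removed it was 0.891. A candidate explanation is an activity level that differs between arrays of the same group, with shock array 5 high and cocaine array 6 low. Glucocorticoid-induced genes were scored here without Dusp1, which is also an immediate early gene. They gave r = 0.779 (exact permutation p = 0.0456, adjusted p = 0.114) and rho = 0.964 (exact permutation, adjusted p = 0.00694). Their r was 0.794 without the same arrays and 0.879 with group means removed. The vascular score gave r = -0.663 with the immediate early genes (exact permutation p = 0.105, adjusted p = 0.131), which was -0.039 without shock arrays 4 and 6 and so rests on them. The astrocyte score gave r = -0.108 with the immediate early genes (adjusted p = 0.787) and 0.702 with the vascular score (adjusted p = 0.129).

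The 17824 probe sets without a single gene symbol were tested apart from the genes. By limma 0 passed an adjusted p under 0.05 (smallest adjusted p = 0.335). An unadjusted p under 0.05 was reached by 639, fewer than the share of 0.05 expected with no difference, and 205 of these differed at least 1.5-fold. Other splits of the arrays were not counted for these probe sets, so chance is not excluded for the 205.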
